A study of Homo sapiens with 8 samples.

How the data were processed

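RNA was measured in 8 libraries of A673 Ewing sarcoma cells, 4 with an shRNA against luciferase and 4 with an shRNA against KDM1A, after retroviral infection with a puromycin vector and 4 days of selection, per the labels' protocols. Total RNA was made into libraries with the ScriptSeq kit, per the labels. bcl2fastq, STAR 2.5.0c, HTSeq and DESeq2 and the genome build GRCh38.p5 are named per the submitters' processing notes, without their roles, and the annotation, strand setting and filters are not given in the sources used here. Because the strand setting is not stated, it is not known whether reads of overlapping and antisense genes were told apart.

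The deposited table held 44089 genes. Its 8 library columns were a score, namely read counts that the authors had divided by 1 factor per library and rounded to whole numbers, called normalized read counts here. That reading rests on the values: each library skipped or doubled whole numbers at a spacing of its own, median-of-ratios factors computed on the columns were 1.0033 to 1.017, and the log2 ratio of the group means followed the authors' unmoderated fold change with r = 0.999983 across 10768 genes with both means above 50 (genes are not independent replicates). The spacing gave the depth of each library as inferred reads. The fold changes in the deposited table are the authors' own, signed so that positive values are higher with KDM1A shRNA. The p-value column in the deposited table is the authors' adjusted p.

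The design fixed before the data were examined assumed raw counts and a count model. As the values were already normalized, limma 3.58.1 in R 4.3.3 was used in its place, on log2(value + 1), and fold changes are on that scale, which understates the change of low genes. A gene was tested when at least 4 libraries had a value of 10 or more, which left 15000. Each was fitted on group with all 8 libraries, with moderated variances and a mean-variance trend, and p-values were adjusted by Benjamini and Hochberg at an FDR of 0.05. Shares and totals were compared with exact two-sided permutation tests over 70 assignments.

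Gene lists, 24 in number, were also fixed before the data were examined: ATF4 and unfolded-protein response, ER chaperones and degradation, NRF2 and heme, EWS-FLI1 activated, EWS-FLI1 repressed, KDM1A partners, DNA replication, mitosis, interferon, hemoglobin and erythroid, p53 targets, apoptosis, cholesterol synthesis, glycolysis and hypoxia, heat shock, NF-kB, neural, ribosomal protein, mitochondrially encoded and replication-dependent histone genes, and markers of epithelial cells, fibroblasts, leukocytes and endothelium. They were tested in limma with camera at a preset correlation of 0.01, adjusted over the 22 lists with at least 2 tested members. The same tests with an estimated correlation and with fry were alternatives. Named genes were chosen by a rule fixed with the lists: KDM1A; the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those past the FDR, with a mean of at least 5 CPM and no overlap between groups; up to 3 members with the smallest p from each of the first 10 lists and 1 from each other list; and TGFBR2, LOX, NR0B1, NKX2-2, DDIT3, HSPA5 and HMOX1. Some genes the rule chose are not reported here.

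The procedure was tested on simulated data for the KDM1A shRNA against luciferase shRNA comparison, with 14589 genes and 50 genes changed at each fold. It recovered 66% of changes of 1.25-fold, 82% of 1.5-fold, 88% of 2-fold and 100% of 4-fold, with 9 false among 177 calls. These rates hold for few changed genes and need not hold where most genes differ. Alternatives covered other scalings, filters, pseudocounts, variance models, thresholds, the replicate number as a block and leaving out each library. No spike-in standard is described in the labels, so a change in total RNA per cell would not be seen by any scaling. A single hairpin sequence per group is implied by the labels, so effects of the hairpin outside KDM1A are not separated from those of KDM1A. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.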

Results

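The data came from A673, an established human Ewing sarcoma cell line whose growth depends on the EWS-FLI1 fusion transcription factor. Cells carried a retroviral short hairpin RNA (shRNA) against either luciferase, a gene human cells lack, or KDM1A (also called LSD1), which removes methyl groups from lysine 4 of histone H3. Each group held 4 libraries of total RNA taken after 4 days of drug selection, described by the submitters as biological replicates. Inferred depth, in 1e6 reads, was 15.7, 12.6, 9.02 and 11.02 in the luciferase libraries and 10.4, 13.6, 14.2 and 10.9 in the KDM1A libraries. The group means were 12.1 ± 2.83 and 12.3 ± 1.91 in the same unit (SD, n = 4 each; exact two-sided permutation p = 0.971). Replicates of a group differed by more than sampling noise in every pair, with chi-square per degree of freedom of 1.85 to 6.03. The first principal component carried 89.2% of the variance and separated the groups, and the second carried 2.31% and set luciferase replicate 3 apart at -29.3.

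The comparison asks how the transcriptome of Ewing sarcoma cells responds to loss of KDM1A, in a study titled around the stress response of the endoplasmic reticulum (ER). KDM1A itself, on chromosome 1 from 23019443 to 23083691 in GRCh38, stood at a normalized read count of 618 ± 44.6 with its own shRNA against 7380 ± 189 with the luciferase shRNA (SD, n = 4 each). This was 11.95-fold lower, a log2 fold change of -3.58 (SE 0.05; limma adjusted p = 3.38e-22), and lower in 4 of 4 libraries. The target gene therefore moved as the labels state in all 8 libraries.

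**Figure D1:**
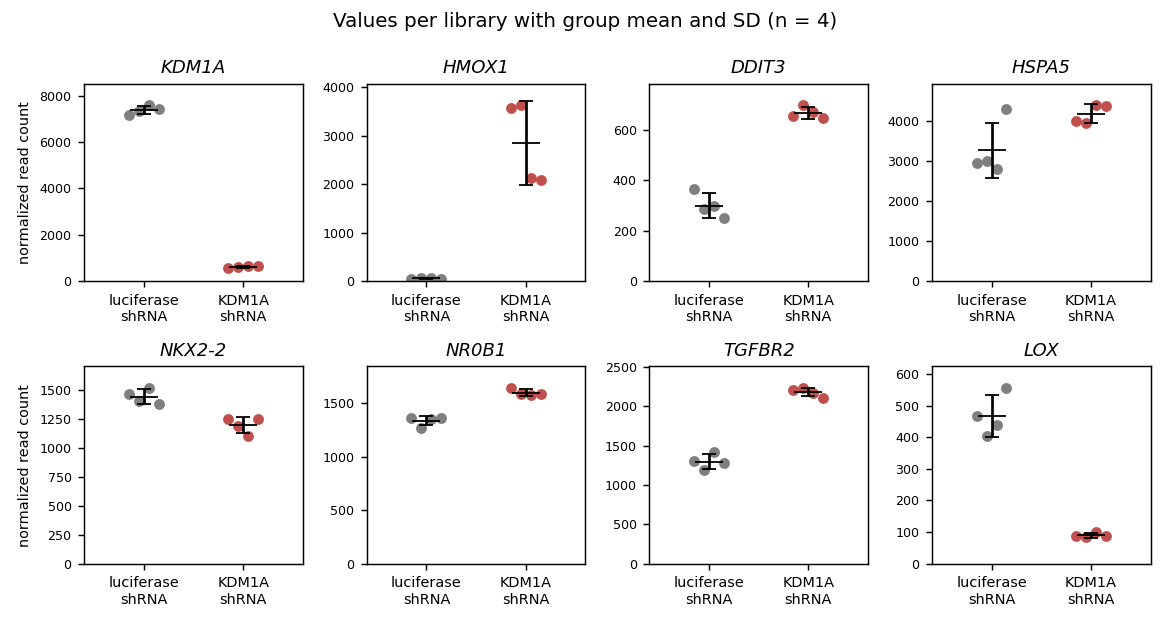
Normalized read counts (vertical axes, linear and starting at 0) of 8 genes in each library, with grey points for luciferase shRNA, red points for KDM1A shRNA, and the group mean with its SD (n = 4). KDM1A fell to 618 from 7380, HMOX1 rose in 4 of 4 libraries, and 1 luciferase library of HSPA5 lies among the KDM1A shRNA libraries.

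Most expressed genes differed between the groups. Of 15000 genes tested, 6152 were higher and 5935 lower with KDM1A shRNA (limma, FDR 0.05), so 80.6% were called, and the median log2 fold change of all tested genes was 0.02. Changes of at least 2-fold numbered 2248 up and 2624 down, at least 4-fold 732 and 809, and at least 8-fold 320 and 219. Among protein-coding genes 5503 rose and 5364 fell of 13031 tested, and among long non-coding RNAs 467 rose and 422 fell of 1391. The 4 values of each group did not overlap for 11157 of the 15000 tested genes (74.4%), called or not, where chance gives 2.86%. All genes named below by the fixed rule were without overlap except HSPA5.

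The highest rise among the protein-coding genes eligible for naming was that of MMP3, a secreted matrix metalloproteinase, from 19.25 ± 5.32 to 3368.5 ± 95.1 (log2 fold change 7.41, SE 0.12). ALPK2, an alpha kinase, rose by a log2 fold change of 6.13, MARCH4, a membrane-bound ubiquitin ligase, by 6.09 and KCNK3, a potassium channel, by 5.95. IL1A, an inflammatory cytokine, rose from 13 to 802.75 (5.90) and VGF, a secreted neuropeptide precursor, from 50.5 to 2948.75 (5.87). ECHDC2 fell from 178.25 to 3.25 (-5.49), ALDH1L1, a folate enzyme, from 1086.5 to 26.75 (-5.31) and VWA1, a matrix protein, by -5.28. CA9, a hypoxia-induced carbonic anhydrase, fell from 373 ± 52.3 to 9.5 ± 2.38 (-5.18), XKR5 by -4.66 and CTSF, a lysosomal protease, by -4.46. Where the lower group mean was small, the size depends on the pseudocount: at 5 in place of 1, the ALPK2 log2 fold change was 5.28, the MARCH4 log2 fold change 5.27, the KCNK3 log2 fold change 4.77 and the ECHDC2 log2 fold change -4.49. Without luciferase replicate 3 the KCNK3 log2 fold change was 5.35.

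**Figure D2:**
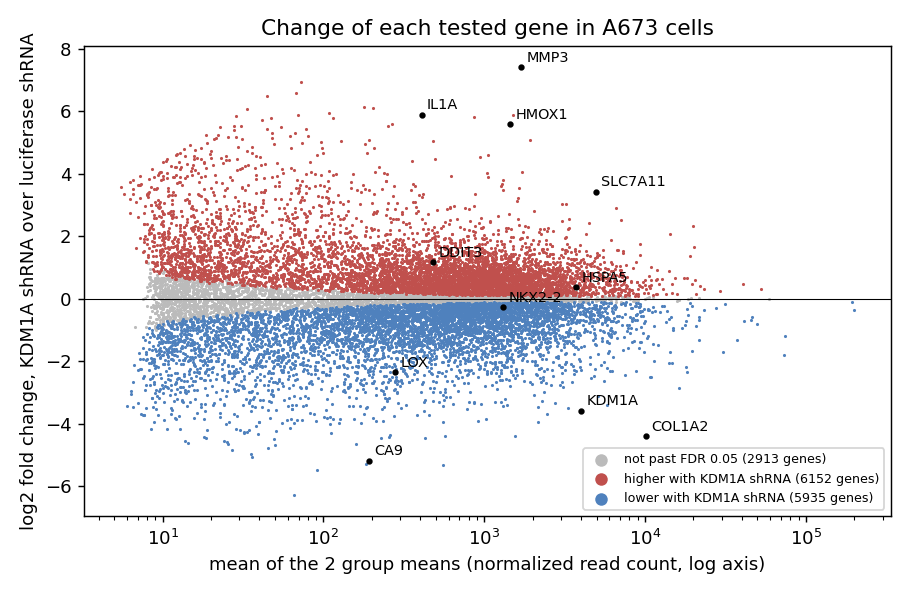
Log2 fold change of each tested gene, KDM1A shRNA over luciferase shRNA (vertical axis), against the mean of the group means in normalized read counts (horizontal log axis). Red marks the 6152 higher genes, blue the 5935 lower genes and grey those not past FDR 0.05, with named genes in black.

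Genes of the ATF4 and unfolded-protein response, the transcriptional program of ER and amino acid stress, moved in both directions. Of 40 tested, 20 rose, 14 fell and 6 did not pass, with the same counts adjusted over the list alone. SLC7A11, the cystine transporter, rose 10.8-fold (9012 ± 1090 against 830 ± 26.8; log2 fold change 3.43, SE 0.06), and DDIT3, the stress transcription factor CHOP, rose 2.25-fold (667 ± 23.1 against 299 ± 49.3; 1.17, SE 0.09; limma adjusted p = 8.68e-11, higher in 4 of 4 libraries). PHGDH, the first enzyme of serine synthesis, fell by a log2 fold change of -2.81 and DDIT4, an inhibitor of mTOR complex signalling, by -3.44. ATF4 itself, named after its value was seen, fell by -0.35. The list median was 0.27 and the list did not pass (limma camera adjusted p = 0.4996, or adjusted p = 0.628 with an estimated correlation).

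ER chaperones and genes of ER-associated degradation were split as well, with 16 rising, 10 falling and 3 not past of 29 tested, also when adjusted over the list alone. DNAJB9, an ER co-chaperone induced by unfolded protein, rose 3.06-fold (668 ± 18.99 against 217.5 ± 12.01; log2 fold change 1.62). ERO1L, the ER oxidase, fell by -1.63 and PDIA4, a protein disulfide isomerase, by -0.73. HSPA5, the main ER chaperone BiP, rose by 0.38 (SE 0.09; 4191.5 ± 237 against 3270 ± 692; limma adjusted p = 0.00053), but luciferase replicate 4, at 4299, lay within the range of the KDM1A shRNA libraries, and the log2 fold change was 0.52 without it. The list median was 0.39 and the list did not pass (limma camera adjusted p = 0.342, or adjusted p = 0.663 with an estimated correlation).

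NRF2 targets and heme metabolism genes, which answer oxidative stress, mostly rose: 13 rose, 6 fell and 1 did not pass of 20, with the same counts adjusted over the list alone. HMOX1, which degrades heme, rose 48.0-fold (2854 ± 869 against 56.75 ± 7.80; log2 fold change 5.59, SE 0.15; limma adjusted p = 2.31e-18). Its 4 KDM1A shRNA libraries read 3576, 3636, 2119 and 2084. MAFG, a partner of NRF2, rose by 2.07 and FTL, the ferritin light chain, by 1.37 to 27429 ± 1445. The list median was 0.76 (limma camera adjusted p = 0.0211), a call lost at adjusted p = 0.411 with an estimated correlation. FTL has many processed pseudogenes, so its level is uncertain.

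Genes known to be activated by EWS-FLI1 fell on balance. Of 25 tested, 6 rose, 18 fell and 1 did not pass, as they did adjusted over the list alone. PPP1R1A, a phosphatase inhibitor, fell by a log2 fold change of -1.91 (596.5 ± 36.5 against 2237 ± 92.8), CAV1, the caveolar coat protein, by -1.33 and BCL11B, a transcription factor, by -1.26. NKX2-2, a homeobox repressor, fell by -0.27 (SE 0.05; limma adjusted p = 8.00e-05, lower in 4 of 4 libraries). NR0B1, an orphan nuclear receptor also activated by the fusion, rose by 0.26 (SE 0.05; limma adjusted p = 2.56e-05, higher in 4 of 4 libraries), while the authors' deposited table gives it an adjusted p of 0.0678. The list median was -0.36 (limma camera adjusted p = 0.0183), a call lost at adjusted p = 0.202 with an estimated correlation.

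Genes known to be repressed by EWS-FLI1 changed strongly but not in one direction: 12 rose and 10 fell of 22, and the counts were the same adjusted over the list alone. TGFBR2, a receptor for transforming growth factor beta, rose by a log2 fold change of 0.75 (SE 0.05; limma adjusted p = 1.36e-11, higher in 4 of 4 libraries). COL1A2, a collagen chain, fell by -4.39 (920.5 ± 80.8 against 19287 ± 321), TGFBI, a matrix adhesion protein, by -2.41 and LOX, the enzyme that cross-links collagen, by -2.35 (SE 0.10; limma adjusted p = 7.10e-15, lower in 4 of 4 libraries). The median of 0.49 and the mean were positive and fry pointed down, and the list did not pass (limma camera adjusted p = 0.626, or adjusted p = 0.670 with an estimated correlation).

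Partners of KDM1A in the CoREST, NuRD and related complexes fell more often than they rose, with 4 rising, 18 falling and 5 not past of 27, the same adjusted over the list alone. RCOR2, a CoREST subunit, fell by a log2 fold change of -3.16 and HMG20B, another member of that complex, by -1.73. GATAD2A, a NuRD subunit, rose by 1.07. The other genes that rose, named after their values were seen, were SNAI1 (1.38), MBD2 (0.76) and CHD4 (0.55). The list median was -0.27 (limma camera adjusted p = 0.00978), a call lost at adjusted p = 0.311 with an estimated correlation.

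Cell cycle genes fell. All 30 mitosis genes fell, with a median log2 fold change of -1.57, among them UBE2C, an E2 of the anaphase-promoting complex (-2.32), DLGAP5, a spindle protein (-2.27), and ASPM, which acts at spindle poles (-2.13). Of 34 DNA replication genes 28 fell, 4 rose and 2 did not pass (median -0.71), with LIG1, a DNA ligase, at -1.80, GINS1, part of the replicative helicase, at -1.70 and TK1, thymidine kinase, at -1.81. The 4 that rose, named after their values were seen, were ORC6 (0.97), CCNE1 (0.89), CCNE2 (0.32) and GINS3 (0.29). All 15 replication-dependent histone genes fell (median -2.32), and HIST1H2AG, the member with the smallest p, stood at -2.62 (1547.5 ± 38.1 against 9520 ± 243). Counts were the same adjusted over each list alone. The limma camera adjusted p was 7.55e-14 for mitosis, 5.75e-06 for replication and 7.04e-10 for histones. With an estimated correlation all 3 calls were lost, at adjusted p = 0.202, 0.361 and 0.172. Histone genes are near-identical copies, so their single levels are uncertain.

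Metabolic lists fell as well. Of 22 glycolysis and hypoxia genes 19 fell and 3 rose (median log2 fold change -1.39), and PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by -4.39 (138.75 ± 6.40 against 2949.5 ± 331). The 3 that rose, named after their values were seen, were SLC2A3 (1.95), NDRG1 (1.13) and VEGFA (0.39). Of 21 cholesterol synthesis genes 17 fell, 1 rose and 3 did not pass (median -0.72). Both counts were the same adjusted over the list alone. The limma camera adjusted p was 1.46e-05 for glycolysis and hypoxia and 3.75e-05 for cholesterol. Both calls were lost with an estimated correlation, each at adjusted p = 0.202.

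Inflammatory genes rose. Of 17 targets and members of the NF-kB pathway 16 rose and 1 fell (median log2 fold change 2.55), with ICAM1, a leukocyte adhesion molecule, up by 4.54 (1806 ± 227 against 77.25 ± 14.4). The 1 that fell, named after its value was seen, was PTGS2 (-1.18). The list passed (limma camera adjusted p = 9.68e-06), a call lost at adjusted p = 0.131 with an estimated correlation. Interferon response genes split, with 8 rising, 14 falling and 2 not past of 24 (median -0.41): DDX58, a viral RNA sensor, rose by 1.63, while OAS1, an antiviral enzyme, fell by -1.49. That list did not pass (limma camera adjusted p = 0.519, or adjusted p = 0.628 with an estimated correlation). Counts were the same adjusted over each list alone.

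Apoptosis regulators rose in 13 cases, fell in 6 and did not pass in 1 of 20 (median log2 fold change 0.53; limma camera adjusted p = 0.0755, or adjusted p = 0.355 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose by 3.79. Of 19 p53 target genes 10 rose, 7 fell and 2 did not pass (median 0.21; limma camera adjusted p = 0.625, or adjusted p = 0.663 with an estimated correlation), and DDB2, a DNA damage sensor, fell by -2.57. Of 15 heat shock genes 7 rose, 5 fell and 3 did not pass (median 0.25; limma camera adjusted p = 0.519, or adjusted p = 0.663 with an estimated correlation), and HSPH1, a chaperone of the HSP110 family, rose by 1.56. Neural genes were even, with 7 up, 7 down and 2 not past of 16 (median 0.19; limma camera adjusted p = 0.733, or adjusted p = 0.726 with an estimated correlation), and VGF was the member with the smallest p. Counts in these 4 lists were the same adjusted over each list alone.

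Ribosomal protein genes fell modestly, 19 of 27 against 2 that rose and 6 not past (median log2 fold change -0.32; limma camera adjusted p = 0.000237), a call lost at adjusted p = 0.202 with an estimated correlation. RPL11 fell by -1.57, and RPL18, named after its value was seen, rose by 0.09. These genes have many processed pseudogenes and their single levels are uncertain. No gene of the 13-member mitochondrially encoded list could be tested, since the deposited table held 24 mitochondrial rows, of which 0 were protein-coding. Of the hemoglobin and erythroid list 16 of 17 members were below the filter, and HBQ1 fell by -1.84 from 31.5 ± 7.85 to 8 ± 1.83. The ribosomal protein counts and the fall of HBQ1, the only tested member of its list, were the same adjusted over each list alone.

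Markers of other cell types were mostly low or mixed. Of 18 fibroblast and stromal markers tested 5 rose, 11 fell and 2 did not pass (median log2 fold change -0.62; limma camera adjusted p = 0.342, or adjusted p = 0.516 with an estimated correlation), and THY1, a surface glycoprotein, rose by 1.89 to 9676 ± 433. Only 3 epithelial markers were tested, of which 0 rose, 2 fell and 1 did not pass in limma (2 of the 3 also changed when adjusted over the list alone), with KRT8, a keratin, at -1.26; the list did not pass (camera adjusted p = 0.330, or adjusted p = 0.411 with an estimated correlation). Of 7 leukocyte markers 3 rose, 2 fell and 2 did not pass (limma camera adjusted p = 0.519, or adjusted p = 0.628 with an estimated correlation), with CD68, a lysosomal protein, at 1.29. Of 9 endothelial markers 5 rose, 3 fell and 1 did not pass (limma camera adjusted p = 0.823, or adjusted p = 0.840 with an estimated correlation), with EMCN, a sialomucin, at -1.68. The endothelial median of 0.59 and camera pointed up and fry pointed down.

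**Figure D3:**
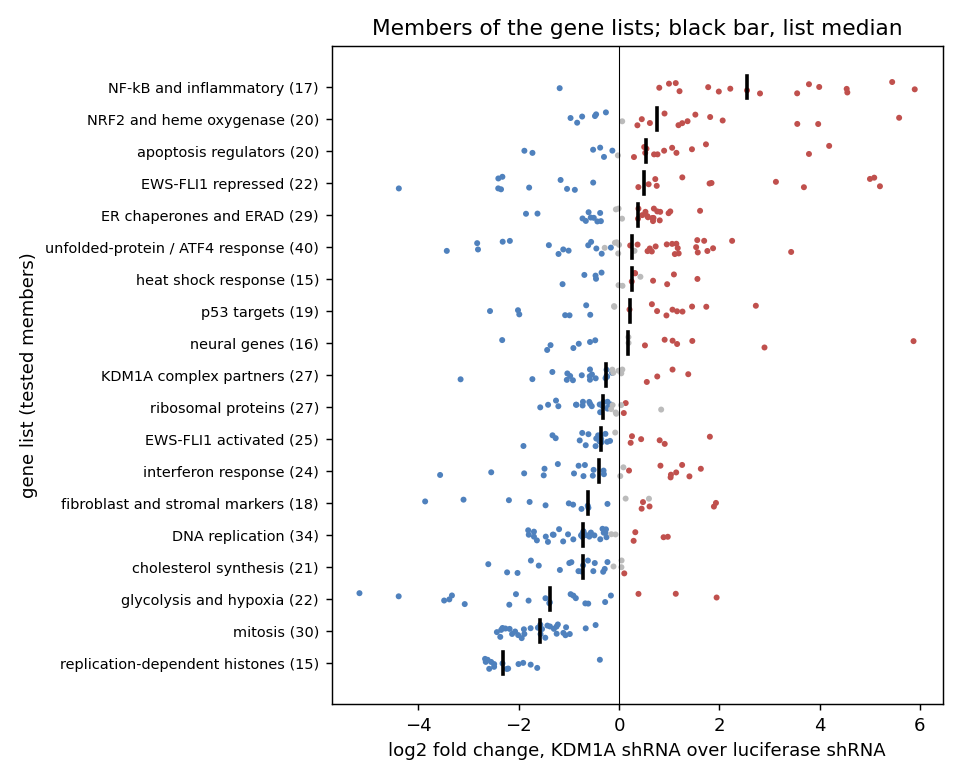
Log2 fold change, KDM1A shRNA over luciferase shRNA (horizontal axis), of each tested member of the gene lists with at least 15 tested members (vertical axis, number tested in brackets). Red points rose, blue points fell, grey points did not pass FDR 0.05, and the black bar is the list median, from 2.55 for NF-kB genes to -2.32 for histone genes.

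Over the 22 lists with at least 2 tested members, 10 passed with the preset correlation (limma camera) and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. The fry test passed 21, but it does not compare a list with other genes.

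The composition of the libraries was compared over 13 shares of counts, of which 6 reached the smallest exact p the design allows and 0 passed Benjamini-Hochberg adjustment (exact adjusted p = 0.0619 for those 6, with no overlap between the groups). With 6 of 13 shares at that smallest p, none can pass the adjustment, so the 0 does not show that composition was unchanged. The share of counts in the 10 most abundant genes was 4.81 ± 0.14% with KDM1A shRNA against 6.43 ± 0.19%, and that in ribosomal protein genes 1.90 ± 0.017% against 2.23 ± 0.061% (SD, n = 4; exact two-sided permutation p = 0.0286 for each, the smallest that 70 assignments allow). RNase P RNA held 1.21 ± 0.075% against 1.48 ± 0.13%, and long non-coding RNA 0.817 ± 0.0092% against 0.751 ± 0.013% (exact p = 0.0286 for each). Leaving out any of KDM1A shRNA replicates 1, 2, 3 and 4 moved the RNase P RNA difference to between -0.292 and -0.235 percentage points, with an exact p of 0.0571 and no overlap between the groups. Shares of miscellaneous RNA (0.173 against 0.135%) and microRNA (0.00270 against 0.00187%) had the higher means with KDM1A shRNA (exact p = 0.0286 for each). The exact p values ranged from 0.114 to 0.571 (adjusted 0.212 to 0.571) for protein-coding, pseudogene, small nuclear, small nucleolar, RNase MRP, transfer and mitochondrial RNA. The mitochondrial share covers no protein-coding gene. Deposited totals, in 1e6 normalized counts, were 14.4 ± 0.020 against 15.1 ± 0.098 (exact p = 0.0286).

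The authors' deposited table gives an adjusted p for 24076 genes, of which 6226 were higher and 5745 lower at 0.05 in that table. Of the 12087 genes called here, 10746 were called in the authors' deposited table in the same direction and 0 in the opposite one, and 1341 were called here alone. A further 1223 calls of the authors' deposited table fell on genes not tested here.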

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

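The tests of GC content, neighbouring genes, RNA without a poly(A) tail and the TMM, median-of-ratios and quantile scalings were chosen only after the result was seen, and those of the second gene sets after the first lists were seen to fall but before the values of the second sets were.

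Single libraries far from the other 3 of their group were found 11 times in 190 groups tested, where chance gives about 1 in 20, by Dixon's ratio of gap to range. In the KDM1A shRNA libraries these were the log2 values of ECHDC2 in replicate 2 (ratio 1), CA9 in replicate 1 (0.839), XKR5 in replicate 4 (0.832), PPP1R1A in replicate 1 (0.890), GATAD2A in replicate 3 (0.893), DDX58 in replicate 1 (0.944) and HIST1H2AG in replicate 2 (0.859). In the luciferase libraries they were PPP1R1A in replicate 4 (0.866), NR0B1 in replicate 2 (0.879), the pseudogene share in replicate 1 (0.882) and the mitochondrial share in replicate 3 (0.841).

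The breadth of the change, 12087 of 15000 genes, was tested against technical causes. Only 1 of 35 splits, the real one, gave 6152 higher genes or 5935 lower genes, against 0 in the highest other split (limma). The other splits had up to 488 genes at unadjusted p under 0.05 (limma). Each of them mixes the groups, so the real contrast adds to its spread and makes calls unlikely. The splits therefore do not exclude chance beyond that 1 in 35. The lowest count over other scalings was 12050. Those scalings moved the median log2 fold change by only -0.03 to 0.05, so they could hardly lower the count and do not decide on scaling. Removing a GC trend left 11107 called genes against 10983 before removal (13354 genes with a GC value). Median log2 fold changes over GC deciles ran only from -0.12 to 0.09, which argues against a GC trend as the whole cause. Windows of neighbouring genes with a shifted median held 6.32% of called genes (2.03% of genes on average over 100 permutations of gene order). That share argues against another karyotype as the whole cause. A change in total RNA per cell and effects of the hairpin outside KDM1A stay open and untested. Any difference between the groups in infection, culture or library preparation cannot be told apart from the shRNA, since the labels give no batch.

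For the number of lists past the threshold, 4 of 35 splits gave as many as the 10 of the real one, itself included (highest other 10), so chance is not excluded by that share. The other splits with 10 were among the 16 that keep 3 libraries of a group together and so hold part of the real contrast, which gave 7 to 10 lists. The 18 splits with equal numbers of both groups on each side gave at most 1.

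The fall of mitosis and histone transcripts may reflect fewer dividing cells. A second set of mitosis genes, fixed with the fall of the first already known, fell in 97.0% (32 of 33, median -1.32; CENPN rose). A lower yield of RNA without a poly(A) tail is argued against for histones by the median of 0.00591 (log2, SE of the mean 0.148, 9 genes) of abundant RNA of that kind. Those 9 genes were mixed, with 2 higher, 4 lower and 3 not past the FDR, and ran from -0.63 to 0.60. Slower division and lower transcription of these genes per cell were not separated, and no cell counts per group were used here.

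The fall of glycolysis and hypoxia transcripts may reflect less oxygen limitation in the KDM1A shRNA cultures. In a second set of hypoxia-induced genes 85.2% fell (23 of 27, median -1.37; ANGPTL4 rose). BHLHE40, left out of that set because it was already known to be higher, brings the share to 82.1%. Fewer cells per dish and lower HIF activity caused by the knockdown remain open, since neither was measured.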

How the results depend on the processing

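The pseudocounts, variance models, TMM, median-of-ratios and quantile scalings were chosen after seeing the data, and the other alternatives were planned. Over scalings, filters, pseudocounts and fits, higher genes numbered 5867 to 7150 and lower genes 5586 to 6567. Leaving out each library gave 5977 to 6118 and 5758 to 5853. The scalings called 12050 to 12089 genes, moved the median by -0.03 to 0.05 and turned no sign of a named gene or list. Asking for a 2-fold change left 2248 higher and 2624 lower, a stricter criterion by construction. KDM1A ran from -3.62 to -3.53. Each of 1180 values of 59 named genes kept its side and direction, and the folds of ALPK2, MARCH4, KCNK3 and ECHDC2, each with a low group mean, moved by over 1.5 times. Of 484 list values 460 kept theirs, 10 were lost, all with the estimated correlation, and 11 were newly past, 10 of them with fry. The median log2 fold change of the list EWS-FLI1 repressed was 0.49 under each, but its test pointed up in camera and down in fry, which passed (limma fry adjusted p = 0.00592). The endothelial test, past in no case, turned down with fry and with the filter of at least 1 CPM in 4 libraries. With the estimated correlation 0 lists passed in limma camera (3 at unadjusted p under 0.05), and with fry 21, which tests another question. For RNase P RNA (percent of counts in RNase_P_RNA) the difference ranged from -0.327 to -0.224 percentage points leaving out each library. Without any one KDM1A library the exact p was 0.0571, although the groups did not overlap, since 1 other of the 35 assignments gave a larger difference. That assignment sets luciferase replicate 3 with the KDM1A libraries, against luciferase replicates 1, 2 and 4. Those luciferase replicates again had the higher share, and only the label of the sides turned the sign. The replicate block gave 6118 genes higher with KDM1A shRNA and 5906 genes lower with KDM1A shRNA. Same-numbered libraries correlated at -0.01, 0.00, 0.01 and -0.01 in their deviations from the group mean, so the values showed no pairing by number. Whether same-numbered libraries were prepared together is not stated in the labels. The planned count models (edgeR quasi-likelihood, DESeq2, and voom with TMM) were not run, since the deposited values are not counts. Reads inferred from the spacing were used only for depth and the comparison of replicates. Upper-quartile factors, totals and, in place of RLE, median-of-ratios factors were computed on the deposited values and tested in limma. At this depth and group size, 66% of the smallest simulated fold were found. The simulation changed 200 genes and gave all genes the same dispersion, whereas 12087 genes were called in the data. Its recovery need not hold for this comparison. Which of depth, group size, spread and number of changed genes limits it was not tested.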

Other observations

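These families were chosen only after the results were seen, and all tests in this part are of that kind. Zinc finger (ZNF) genes on chromosome 19, most of them DNA-binding repressors in large clusters, rose on balance: 142 of 220 tested rose, 24 fell and 54 did not pass in limma (median log2 fold change 0.47, 0.45 to 0.55 over the scalings). They passed in limma camera (adjusted p = 2.74e-06, or adjusted p = 0.0149 with an estimated correlation). ZNF genes elsewhere were less one-sided in number, with 113 up, 74 down and 40 not past of 227 (median 0.15), and did not pass (limma camera adjusted p = 0.132, or 0.218 with an estimated correlation); the difference between both sets was not tested. Clustered protocadherins, neural adhesion genes, rose in 28 cases, fell in 7 and did not pass in 15 of 50 (median 0.64; limma camera adjusted p = 0.0173, a call lost at adjusted p = 0.120 with an estimated correlation). All 60 tested genes named HIST fell (median -2.27; limma camera adjusted p = 4.24e-25, or adjusted p = 0.0263 with an estimated correlation). Genes in such families resemble each other, so single levels are uncertain.

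Of 288 windows of 50 or more neighbouring genes, 16 had a median log2 fold change beyond 0.4 in size, holding 6.32% of called genes, where permuting the gene order put 2.03% of genes in such windows on average. On chromosome 6 the windows from 17615035 to 26199988 and from 26204645 to 27893891, which hold the large histone cluster, had medians of -1.30 and -2.10. On chromosome 19, 4 windows had medians of 0.41 to 0.49, and on chromosome 5 the window from 139395940 to 141186221, which holds protocadherin genes, had 0.58. Also on chromosome 5, the next window, from 141187127 to 144485686, had 0.42, and that from 173056349 to 181272307 had 0.49.

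Several genes were listed at 0 or 1 in all 8 libraries, among them CD99, HYOU1, HSPA1A, RPS9, RPS18, RPL7A and RPS25. In total 8 of 86 ribosomal protein genes were at most 1 in every library. In the interval from 28 to 34 Mb of chromosome 6, 19.05% of 21 protein-coding genes were at most 1 in every library, against 26.4% of 1036 elsewhere on that chromosome. With only 21 genes there, the comparison is a weak check and no conclusion is drawn from it. The cause of the values near 0 was not established, so they do not show that these genes are unexpressed.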
